A study of Homo sapiens with 6 samples.

How the data were processed

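RNA from HaCaT cells, an immortalized human keratinocyte line, was sequenced in 6 libraries, 3 labelled control and 3 labelled palmatine. Groups and replicate numbers were taken from the sample titles and treatment labels. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was selected with oligo(dT) beads, and libraries were made with the NEBNext Ultra II kit. A dUTP step is described there for strand-specific libraries, but the strand setting used in counting is not given in the sources used here. HISAT2 2.1.0 and HTSeq 0.9.1 are named in the submitters' processing notes. The genome build, the annotation release and the treatment of reads that map to several places are not given in the sources used here.

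The deposited table gives raw read counts and FPKM per gene for each library, per the file headers. The counts were whole numbers. The deposited FPKM equalled the count divided by the gene length and by the library's total count, in FPKM units, to a relative tolerance of 1e-05, for 100% of values above 0. The authors' length column was used as given. The table held 20035 genes, of which 19406 had a symbol. Of its gene identifiers, 19851 were found in GENCODE release 29, and 100% of these overlapped the same locus on the same strand, so that coordinates below follow GRCh38 although the table names no build. Of these genes, 19738 were protein-coding.

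Genes were kept with filterByExpr in edgeR 4.0.16 (minimum count 10), which left 12356 genes. Libraries were scaled with TMM factors, which ran from 0.970 to 1.04. Palmatine was compared with control by the edgeR quasi-likelihood test with robust dispersion estimates, in R 4.3.3, with no covariates. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Levels are given as CPM on the TMM-scaled library sizes, as mean ± SD. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic, and intervals are 95% intervals.

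Gene lists, 29 in all with 737 entries, were fixed before the data were examined, as were the test, the named genes' rule and most of the alternative settings. Each list with at least 3 tested members, 27 in all, was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The number of alternatives given for a list covers only settings that kept the preset correlation. For each list, the mean of centred log2 CPM per library was also compared by an exact permutation test, whose smallest possible p for 3 against 3 libraries is 0.1. The named genes' rule took up to 10 genes per direction with the largest change past the threshold, a symbol, a mean FPKM of at least 1 and no overlap between groups. It also took up to 5 genes per direction with the smallest adjusted p (where none passed, the 5 with the smallest p, as values) and up to 4 members per list with the smallest p. LCK, RELA, NFKB1, CTNNB1, GSK3B, AXIN2, IL17RA, IL17RC, ACTB and GAPDH were included whatever their values. Other genes named were chosen after their values were seen.

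The alternatives covered other scaling factors, DESeq2 1.42.0, limma-voom, looser and stricter count filters, limma on log2(FPKM + 1) with other pseudocounts, filters and normalizations, other thresholds, a replicate block, each library left out in turn, the 10 most abundant genes left out and protein-coding genes alone. Added after the data were seen were fits with per-library loess trends (span 0.3) on gene length, on transcript GC share, or on both removed as offsets, and a fit without the mitochondrially encoded genes. GC shares were taken from the longest GENCODE 29 transcript and were found for 99.9% of tested genes.

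The procedure was tested on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed. Without any trend between libraries, edgeR recovered 80.6% of genes changed by 1.5-fold, 95.5% of those changed by 2-fold and 98.4% of those changed by 3-fold. This was among 12282 genes, with 13 false calls. With an added length trend of assumed size between libraries, the shares were 4.48% at 1.5-fold and 65.2% at 2-fold among 12268 genes. Removing the trend brought them to 73.1% and 92.4%. The added trend was nearly the same on average in both groups, whereas the real fold changes followed gene length. These shares are therefore not the power of the real comparison. Intervals and floors given for counts cover counting error only, since PCR copies are not independent molecules. One line of the table was left out beforehand and was not analysed here.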

Results

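Transcript levels were measured by poly(A) RNA sequencing in HaCaT cells, an immortalized human keratinocyte line that is widely used as a model of the epidermis. Libraries came from 3 control samples and 3 samples treated with palmatine, a protoberberine plant alkaloid. The series describes cells stimulated with interleukin 17 (IL-17), a cytokine that drives psoriatic inflammation, and names the kinase LCK and the NF-kB and Wnt pathways as its subject. The control samples carry the treatment label none, so whether they received IL-17 is not stated. Total counts ran from 12908646 to 17218171 per library. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

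The libraries were similar to one another, with Pearson correlations of log2 CPM from 0.985 to 0.996. The median correlation was 0.993 within groups and 0.992 between groups. Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of at least 3.24, so none was a copy of another; this does not show whether they came from separate cultures. The first principal component held 51.0% of the variance and did not separate the groups: control 2, control 3 and palmatine 2 lay on one side and control 1, palmatine 1 and palmatine 3 on the other. Gene loadings on this component were related to gene length across genes, which are not independent replicates (absolute Spearman correlation 0.502), and the palmatine log2 fold changes followed length as well (Spearman correlation 0.443).

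The comparison of palmatine with control asked which transcripts differ between these groups of keratinocyte libraries. If the controls received no IL-17, the comparison cannot tell palmatine apart from IL-17. Palmatine-treated cells had lower levels of 4 mitochondrially encoded transcripts of respiratory complex I and of CYP1A1, a xenobiotic-metabolizing monooxygenase induced by the aryl hydrocarbon receptor. MT-ND1 was 3.58 times lower, falling from 5670 ± 948 CPM to 1582 ± 101 CPM (SD, n = 3 per group). MT-ND2 was 2.90 times lower, MT-ND6 2.51 times and MT-ND5 2.32 times. CYP1A1 was 2.60 times lower, at 58.0 ± 5.68 CPM in control and 22.4 ± 1.89 CPM in palmatine cells (SD, n = 3 per group). These 5 genes were the only ones of 12356 tested to pass the threshold in edgeR, and none was higher in palmatine.

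The log2 fold change of MT-ND1 (ENSG00000198888, mitochondrial genome positions 3307 to 4262) was -1.84 with a standard error of 0.122 (adjusted p = 0.000439, edgeR quasi-likelihood test). That of MT-ND2 (ENSG00000198763, positions 4470 to 5511) was -1.54 ± 0.103 (SE, adjusted p = 0.000439). MT-ND5 (ENSG00000198786, positions 12337 to 14148) had a log2 fold change of -1.21 ± 0.0986 (SE, adjusted p = 0.00131) and MT-ND6 (ENSG00000198695, positions 14149 to 14673), which is encoded on the opposite strand, one of -1.33 ± 0.117 (SE, adjusted p = 0.00204). CYP1A1 (ENSG00000140465, chromosome 15, positions 74719542 to 74725536) had a log2 fold change of -1.38 ± 0.0997 (SE, adjusted p = 0.000618). For each of these 5 genes, the 3 palmatine values lay below the 3 control values; of all tested genes 12.4% had groups without overlap, against 10% by chance. At an unadjusted p under 0.05, 634 genes were higher and 579 lower, where 618 in all were expected by chance. These counts rested on single libraries and on scaling: they were 172 and 129 without palmatine replicate 1, 194 and 164 without palmatine replicate 3, 198 and 166 without control replicate 3, 285 and 257 without control replicate 2, 1461 and 1267 without control replicate 1 and 1556 and 1678 without palmatine replicate 2. With library size alone they were 1539 and 179, and with FPKM rescaled to TPM 4422 and 30. DESeq2 called 0 genes higher and 14 lower, and limma-voom 0 higher and 5 lower.

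No gene passed the threshold as higher in palmatine. The 5 with the smallest p all had an adjusted p of 0.455 in edgeR. FGF1, a fibroblast growth factor, was at 5.81 ± 0.373 CPM in control and 8.97 ± 0.789 CPM in palmatine cells (SD, n = 3 per group). The log2 fold changes were 0.63 for FGF1, 0.72 for TCAF2, 0.43 for LRP4, a Wnt-modulating receptor, 0.69 for CASTOR2, a relative of an arginine sensor of the mTORC1 pathway, and 0.69 for BCL11B, a zinc-finger transcription factor.

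Among the 13 mitochondrially encoded mRNAs, which code for subunits of the respiratory chain and ATP synthase, 4 fell and 9 did not pass the threshold over all genes; adjusted over the list alone, 9 were lower and 0 higher. Mitochondrially encoded genes as a list were lower in palmatine, with a mean log2 fold change of -0.72 and a median of -0.45 (camera adjusted p = 6.8e-15; adjusted p = 0.277 with an estimated correlation). The list was called under 27 of 28 alternatives; with quantile-normalized FPKM the mean relative to all genes was -0.12 (adjusted p = 0.599). The members differed widely. MT-ND4L, also of complex I, had a log2 fold change of -0.17 (adjusted p = 0.586 in edgeR), and its sign changed under 4 of 30 alternatives. MT-CO1, MT-CO2 and MT-CYB, of complexes IV and III, had log2 fold changes of -0.36, -0.41 and -0.45; DESeq2 called these 3 lower as well (adjusted p = 0.00688, 0.000535 and 3.14e-06), and 9 of the 13 in all, while their highest adjusted p over 29 alternatives were 1, 1 and 0.932 and the sign for MT-CYB changed under 1. MT-ND4, which also codes for a complex I subunit, was at 6371 ± 656 CPM in control and 6496 ± 578 CPM in palmatine cells, with a 95% interval of the log2 fold change from -0.21 to 0.26 (SD, n = 3 per group). MT-ATP6 had a log2 fold change of -0.06 and MT-CO3 one of -0.16; the sign changed under 3 of 29 alternatives for MT-ND4, 10 of 30 for MT-ATP6 and 3 of 29 for MT-CO3. MT-ND3 was at 1423 ± 273 CPM in control and 713 ± 150.0 CPM in palmatine cells (SD, n = 3 per group; adjusted p = 0.295 in edgeR); it was called under 4 of 30 alternatives, namely DESeq2, the replicate block and the fits with length or both trends removed, with an adjusted p from 3.14e-06 to 1. MT-ATP8 had a log2 fold change of -0.86 (edgeR adjusted p = 0.0686; 0.0383 without palmatine replicate 1, and from 7.77e-08 to 0.485 over 30 alternatives). The mitochondrially encoded share of all counts was 7.48% ± 0.350 in control and 5.41% ± 0.269 in palmatine libraries (SD, n = 3 per group; exact permutation p = 0.1, the smallest that 3 against 3 allows). Quantile normalization of FPKM, which sets equal ranks to equal values, ended the calls of MT-ND1, MT-ND5 and MT-ND6, at adjusted p of 0.295, 0.516 and 0.211 (limma), each the highest over the gene's alternatives, and made MT-ND4 and MT-ATP6 higher at 0.81 and 0.75. Unfiltered FPKM also ended the calls of MT-ND5 (limma adjusted p = 0.0584) and MT-ND6 (0.0812). Reads of these genes can be shared with nuclear copies, of which GENCODE 29 names from 2 for MT-ATP8 to 45 for MT-CO1, with 35 each for MT-ND1 and MT-ND4, 34 for MT-ND2, 36 for MT-CO3 and 42 for MT-CYB, and overlapping or opposite-strand transcripts cannot be told apart without strand information.

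**Figure D1:**
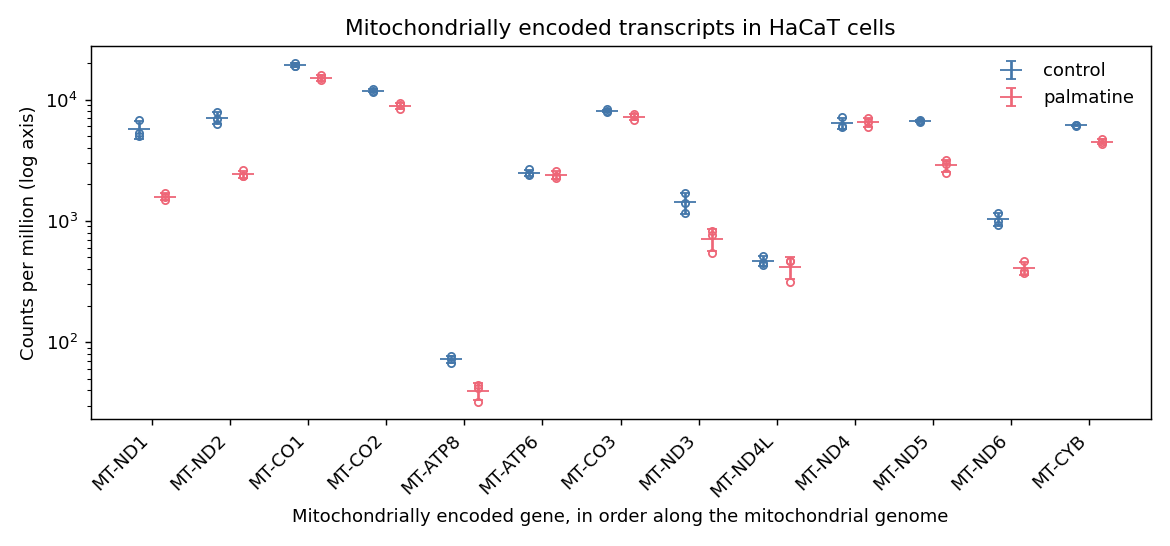
Levels of the 13 mitochondrially encoded mRNAs in CPM (vertical log axis), in order along the mitochondrial genome, in 3 control (blue) and 3 palmatine (red) libraries; circles are libraries, and bars are the mean and SD. MT-ND1 lay at 5670 CPM in control and 1582 CPM in palmatine cells, while MT-ND4 lay at 6371 and 6496 CPM; quantile normalization of FPKM, not plotted, put MT-ND4 higher in palmatine by 0.81 on the log2 scale.

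Targets of the aryl hydrocarbon receptor, a ligand-activated sensor of xenobiotics, were lower in palmatine as a list. Of 11 tested members all 11 had a negative log2 fold change, 1 (CYP1A1) passed over all genes, and 3 were lower when adjusted over the list alone, with 0 higher. The list had a mean log2 fold change of -0.29 and a median of -0.16 (camera adjusted p = 3.21e-05; adjusted p = 0.277 with an estimated correlation; fry adjusted p = 0.018). CYP1B1, a related monooxygenase, was at 350 ± 5.00 CPM in control and 242 ± 20.03 CPM in palmatine cells (SD, n = 3 per group), and its log2 fold change of -0.53 had an adjusted p of 0.0763 in edgeR. ALDH3A1 and NQO1, both detoxifying enzymes, had log2 fold changes of -0.23 and -0.31, each with an adjusted p of 0.455 in edgeR. NQO1 is also a member of the NRF2 oxidative stress response list described below. The target TIPARP had a log2 fold change of -0.10 (adjusted p = 0.512 in edgeR), and AHRR was not tested.

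No NF-kB target passed the threshold at the mRNA level. The series names LCK and the NF-kB and Wnt pathways, but their protein levels and activity were not measured here. Of 34 tested NF-kB target genes, which encode cytokines, survival factors and feedback inhibitors, 0 passed over all genes and 0 over the list alone; edgeR gave 1 higher and 2 lower at an unadjusted p under 0.05. The mean and median log2 fold changes were both 0.01, with the camera test leaning lower (camera adjusted p = 0.966). For 34 of the 34 the 95% interval excluded a 2-fold change. RELA and NFKB1, which encode NF-kB subunits, had log2 fold changes of 0.16 and 0.04. IER3, a stress-inducible NF-kB target, had the smallest p in the list, with a log2 fold change of -0.34 (adjusted p = 0.455).

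Wnt transcripts likewise did not pass. None of the 17 tested Wnt/beta-catenin targets and none of the 39 Wnt pathway components passed, with mean log2 fold changes of 0.03 and 0.07 (camera adjusted p = 0.895 and 0.468); at an unadjusted p under 0.05 edgeR gave 2 higher and 2 lower targets, and 3 higher and 1 lower components. CTNNB1, which encodes beta-catenin, had a log2 fold change of -0.06 and GSK3B, a kinase that marks beta-catenin for degradation, one of 0.18. The transcription factors TCF7L1, the component with the smallest p, and TCF7L2 had values of 1.13 and 0.47, with TCF7L1 at 0.661 ± 0.0282 CPM in control and 1.45 ± 0.596 CPM in palmatine cells (SD, n = 3 per group). The targets RNF43 and SOX9 had values of 0.44 and 0.33, and the targets APCDD1 and FOSL1 -0.29 and -0.19; all 6 of these genes had an adjusted p of 0.455 in edgeR, and the sign for FOSL1 changed under 1 of 31 alternatives. The 95% interval excluded a 2-fold change for 17 of 17 tested targets and 36 of 39 tested components. The list held 28 targets, and AXIN2, LEF1, LGR5, NKD1, NKD2, NOTUM and SP5 were among those not tested, so nothing is shown for them. AXIN2, a widely used Wnt readout, had 1 count in 1 library and 0 in the other 5. The sign of the CTNNB1 change was positive instead of negative under 7 of 31 alternatives.

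LCK, a kinase best known from T cells, was close to the detection floor in these keratinocytes. Each library held 2 or 3 LCK counts, 0.170 ± 0.0223 CPM in control and 0.184 ± 0.0142 CPM in palmatine cells (SD, n = 3 per group), so the gene was not tested and a difference was not detectable at this depth. None of the 15 T-cell markers was tested, and the highest mean level among them was 0.315 CPM. Of the other Src-family kinases and their regulators, 6 were tested and 0 passed, with a mean log2 fold change of 0.06 (camera adjusted p = 0.381); the 95% intervals of all 6 excluded a 1.5-fold change.

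The IL-17 and psoriasis response genes, among them antimicrobial peptides and neutrophil chemokines, did not pass as a list. Of 24 tested members 0 passed over all genes and 1, IL1B, was lower when adjusted over the list alone; edgeR gave 1 higher and 2 lower at an unadjusted p under 0.05. The mean log2 fold change was -0.04 and the median -0.05 (camera adjusted p = 0.498). With FPKM rescaled to TPM the camera adjusted p was 0.0419. With length and GC trends removed the mean was positive, at 0.10 (camera adjusted p = 0.0829). The sign changed under 3 of 29 alternatives. IL1B, an inflammatory cytokine, was at 29.9 ± 2.46 CPM in control and 21.8 ± 1.498 CPM in palmatine cells (SD, n = 3 per group), a log2 fold change of -0.45 with an adjusted p of 0.455 over all genes in edgeR. SERPINB3, a protease inhibitor raised in psoriatic skin, had a value of -0.29, and S100A7A, a calcium-binding relative of psoriasin, one of 0.60, each with an adjusted p of 0.455. The 95% interval excluded a 2-fold change for 22 of 24. The receptor genes IL17RA and IL17RC had values of 0.21 and -0.18. Levels differed widely within the list: 33 of the 37 members in the table had a count, the highest mean level was 731 CPM, DEFB4A had 0 to 3 counts per library, and S100A7 was at 10.3 ± 2.57 CPM in control and 8.34 ± 0.216 CPM in palmatine cells (SD, n = 3 per group).

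Transcripts of the translation and respiration machinery were lower on average in palmatine, but the libraries overlapped. All 40 cytosolic ribosomal protein genes had negative log2 fold changes, with a mean of -0.30 (camera adjusted p = 2.19e-12; adjusted p = 0.595 with an estimated correlation), and 0 passed singly in edgeR, with 16 lower at an unadjusted p under 0.05. RPL35 and RPL32 had values of -0.47 and -0.35. Of 41 nuclear genes for oxidative phosphorylation 39 had negative values, with a mean of -0.20 (camera adjusted p = 2.06e-07; adjusted p = 0.595 with an estimated correlation), and 0 passed singly, with 5 lower at an unadjusted p under 0.05; NDUFC1 of complex I and SDHB of complex II had values of -0.40 and -0.27. Per library, the ribosomal list mean was 0.15 ± 0.20 in control and -0.15 ± 0.25 in palmatine cells on the centred log2 scale (SD, n = 3 per group, exact permutation p = 0.2). This list mean followed the split of the libraries along the first principal component described above, with control 1 at -0.07 and palmatine 2 at 0.11. The respiration list gave 0.10 ± 0.16 and -0.10 ± 0.20 (SD, n = 3 per group; exact permutation p = 0.2).

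**Figure D2:**
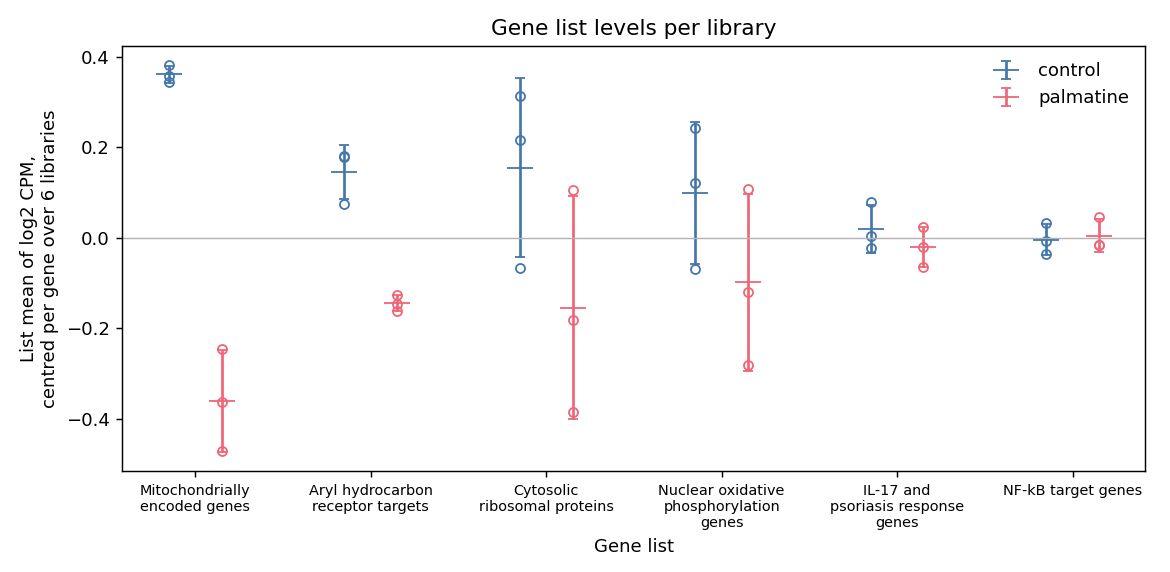
Mean log2 CPM of 6 gene lists per library (vertical axis, centred per gene over the 6 libraries) in 3 control (blue) and 3 palmatine (red) libraries; circles are libraries, and bars are the mean and SD. The groups lay apart for the mitochondrially encoded genes and the aryl hydrocarbon receptor targets and overlapped for the ribosomal list, where control 1 lay at -0.07 and palmatine 2 at 0.11.

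Of the remaining lists, 6 passed with camera, each with small changes and with 0 members called singly; with an estimated correlation each had an adjusted p of 0.595. Lower were the integrated stress response (mean log2 fold change -0.09, camera adjusted p = 0.00159; DDIT3 at -0.47 and SLC3A2 at -0.22), the NRF2 oxidative stress response (-0.16, camera adjusted p = 0.00159; TXN at -0.33), cell cycle and mitosis (-0.06, camera adjusted p = 0.0249) and cholesterol synthesis (-0.08, camera adjusted p = 0.043). Higher were hypoxia and glycolysis (mean log2 fold change 0.08, camera adjusted p = 0.0142) and epithelial-mesenchymal transition and matrix (0.13, camera adjusted p = 0.0337). The hypoxia list had 18 positive and 14 negative values. BNIP3 was at 0.45 and PDK1 at 0.33, while glycolytic enzymes went both ways, with HK2 at 0.22 and GAPDH at -0.18. The matrix list had 13 positive and 6 negative values, with the matrix protein TNC at 0.56 and the collagenase MMP13 at 0.29. It holds epithelial and mesenchymal genes together, so its mean gives no direction of a transition. The epithelial genes CDH1 and CLDN4 were at 0.13 and -0.29, and the mesenchymal CDH2 at -0.01 and FN1 at 0.38. VIM, SNAI1, ZEB1 and ZEB2 were not tested. In all, 10 of 27 lists passed, 8 lower and 2 higher; 0 passed with an estimated correlation and 2 with fry. In edgeR, an unadjusted p under 0.05 was reached by 6 lower genes of the integrated stress response, 5 of the NRF2 response, 1 of the cell cycle and 5 of cholesterol synthesis, by 9 higher hypoxia genes, and by 4 higher and 1 lower matrix genes. Adjusted over the list alone, 0 members of these 6 lists, of the ribosomal list or of the respiration list passed. Without control replicate 1, 6 lists passed. Cell cycle and mitosis lost its call without control replicate 1 (camera adjusted p = 0.0787), control replicate 3 (0.0782) or palmatine replicate 1 (0.0907), and with length and GC trends removed (0.475, mean -0.02); it was called under 15 of 29 alternatives. Cholesterol synthesis and SREBP targets lost it without control replicate 1 (0.108), control replicate 2 (0.376) or palmatine replicate 1 (0.105), and was called under 15 of 29. Hypoxia and glycolysis lost it without control replicate 1 (0.278) or palmatine replicate 2 (0.281), and with both trends removed (0.0902, mean 0.06), and was called under 25 of 29. Epithelial-mesenchymal transition and matrix lost it without control replicate 1 (0.128), control replicate 3 (0.0761) or palmatine replicate 2 (0.207), and was called under 24 of 29. The integrated stress response and the NRF2 list were each called under 28 of 29.

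The lists of keratinocyte state did not pass with edgeR's TMM-scaled values, and 2 of them passed under 1 alternative each. Keratinocyte terminal differentiation had 17 tested members, a mean log2 fold change of -0.02 and a camera adjusted p of 0.381; it passed with FPKM rescaled to TPM (0.0161), and its sign changed under 6 of 29 alternatives. KRT13, a keratin of wet epithelia, had a value of -0.22. Basal and activated keratinocyte genes had 20 tested members, a mean of 0.03 and a camera adjusted p of 0.443, and passed with quantile-normalized FPKM (8.19e-05, at 0.16 relative to all genes), with the anchoring collagen COL7A1 at 0.30 and the activation keratin KRT16 at -0.42. Interferon-stimulated genes had 43 tested members, a mean of 0.01 and a camera adjusted p of 0.925. The reference genes ACTB and GAPDH had log2 fold changes of -0.02 and -0.18 (adjusted p = 0.938 and 0.477), and the sign for ACTB turned positive under 11 of 30 alternatives.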

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

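The fits with length or GC trends removed and the fit without mitochondrially encoded genes were chosen after the data were seen; the other alternatives were planned. Against 5 lower genes, DESeq2 gave 14, the unfiltered counts 8, unfiltered FPKM 3, quantile-normalized FPKM 2, an unadjusted p under 0.05 with a log2 change over 1 gave 10, the replicate block 9, leaving out the 10 most abundant genes 3 (MT-ND2 and MT-ND5 were among those left out), removing the length trend 9, removing both trends 8 and leaving out mitochondrially encoded genes 1. Against 0 higher genes, quantile-normalized FPKM gave 2, FPKM rescaled to TPM 1, and the unadjusted p with a fold threshold 10; TPM moved the median of all genes by 0.18. Against 10 lists, an adjusted p under 0.01 gave 6, an estimated correlation 0 and fry 2. Leaving out each library in turn gave 5 to 6 lower genes, 0 higher genes and 6 to 10 lists, the 6 without control replicate 1; the 5 lower genes were called in each of these fits. MT-ATP6 was higher at 0.75 with quantile-normalized FPKM, where the cell cycle, NRF2 and cholesterol lists also changed sign relative to all genes, at 0.0189, 0.0115 and 0.00902. Apart from what the construction of a setting shows, the cause was not tested.

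CYP1A1 was called under 31 of 31 alternatives, MT-ND2 under 29 of 29, MT-ND1 under 29 of 30, MT-ND6 under 28 of 30 and MT-ND5 under 27 of 29. Of 1704 values of named genes under alternatives, 5 lost a call, 29 gained one and 1 reversed; 44 uncalled values changed sign. Of 766 list values, 37 lost a call, 18 gained one and 3 reversed. Same-numbered libraries had correlations of deviations from group means of 0.40, 0.18 and -0.10, so the numbers were not taken as pairs, and not every library correlated best with its own number. The replicate block gave 9 lower genes, adding CYP1B1, MT-ATP8, MT-ND3 and U2AF1, 0 higher genes and 11 lists. At an unadjusted p under 0.05 in edgeR, the block gave 1268 higher and 1235 lower genes, against 634 and 579 without it. Genes near the floor, such as LCK, are limited by depth: 3 counts correspond to 0.174 to 0.232 CPM.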

Other observations

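Among the lists not yet described, 0 passed with camera. TGF-beta and YAP targets had a mean log2 fold change of 0.04 (camera adjusted p = 0.485). The p53 targets had a mean of -0.02 (camera adjusted p = 0.846), the ER unfolded protein response 0.00 (camera adjusted p = 0.895), immediate-early and AP-1 genes -0.01 (camera adjusted p = 0.283) and replication-dependent histones -0.10 (camera adjusted p = 0.177). Heat-shock genes had a mean of -0.08 (camera adjusted p = 0.0656), with SQSTM1, an autophagy receptor, at -0.33, and metallothioneins one of -0.24 (camera adjusted p = 0.0596). Heat-shock and proteotoxic stress passed without control replicate 2 (camera adjusted p = 0.0385). Metallothioneins passed without palmatine replicate 2 (0.0484) and under 9 of 29 alternatives in all, with an adjusted p from 0.00157 to 0.278. Replication-dependent histones passed under 4 of 29, with an adjusted p from 0.00205 to 0.593, and changed sign under 2. Immediate-early and AP-1 genes passed without palmatine replicate 1 (0.0272). Adjusted over the list alone, 0 members of these lists passed in edgeR. Markers of other cell types were low, and 1 of them, COL3A1, a fibrillar collagen of fibroblasts, was higher when adjusted over the 2 tested fibroblast markers alone, at 0.658 ± 0.103 CPM in control and 1.18 ± 0.224 CPM in palmatine cells (SD, n = 3 per group; log2 fold change 0.83, edgeR adjusted p = 0.0397 over the list and 0.455 over all genes). The highest mean level was 2.90 CPM among fibroblast markers, 2 of which were tested, 4.28 CPM among 3 tested melanocyte markers (camera adjusted p = 0.381) and 6.10 CPM among 4 tested myeloid and endothelial markers (camera adjusted p = 0.966).

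U2AF1, a splicing factor chosen after its values were seen, was at 13.4 ± 2.94 CPM in control and 5.35 ± 0.934 CPM in palmatine cells (SD, n = 3 per group). Its log2 fold change of -1.33 had an adjusted p of 0.0809 in edgeR, which was 0.0168 without control replicate 2 and ran from 1.41e-07 to 0.610 over 24 alternatives. A near-identical copy, U2AF1L5, can share its reads, so the level is uncertain.

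In the patterns below, the tests of equal falls, trends, scaling factors and library differences were chosen after the results were seen, and the counts over other splits before. The fall of MT-ND1, MT-ND2, MT-ND5 and MT-ND6 was set against 3 technical explanations. As to an equal loss of mitochondrial RNA, the 13 log2 fold changes were not equal, with a heterogeneity Q of 408. Chance at equal change of independent genes stays below 26.2 in 99% of cases, but the estimated correlation in this list was 0.371. The 4 calls were already known when this test was chosen, so the test only describes the spread. With length and GC trends removed all 4 stayed called, the change nearest to 0 being -1.03 ± 0.143 (SE, adjusted p = 0.0349 in edgeR) for MT-ND5, whose adjusted p ran from 3.56e-29 to 0.516 over 29 alternatives, and over 6 other scaling factors it was -1.02; quantile normalization, which ties values to ranks, gave -0.24 for MT-ND5. Reads shared with nuclear copies and antisense reads were not tested and stay open, as does an effect of palmatine on these transcripts. Whether oligo(dT) selection captured these transcripts equally in both groups was not tested either. An effect of IL-17 stays open too, as it is not stated whether the controls received it.

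CYP1A1 fell, and CYP1B1 had a log2 fold change of -0.53 (adjusted p = 0.0763 in edgeR, and from 4.59e-06 to 0.645 over 31 alternatives). With length and GC trends removed both were called, the smaller change being -0.56 ± 0.062 (SE, adjusted p = 0.0131 in edgeR), and over 6 other scaling factors the change nearest to 0 was -0.33 for CYP1B1 (highest adjusted p = 0.324). The log2 fold changes of the 11 tested aryl hydrocarbon receptor targets were not equal, with a heterogeneity Q of 162. Chance at equal change of independent genes stays below 23.2 in 99% of cases. CYP1A1 was already known to be called when this test was chosen, so the test only describes the spread. No mechanism was tested, and an effect of palmatine on these genes stays open, as does one of IL-17 if the controls lacked it.

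The lower ribosomal and nuclear respiration lists may reflect differences between libraries rather than palmatine. For the ribosomal list 2 of the 10 splits of the 6 libraries gave a difference as large, the real one 0.31 and the highest other 0.42; for the respiration list 2 of 10 did as well, at 0.20 and 0.31. With both trends removed the differences were -0.25 ± 0.14 and -0.11 ± 0.0936 (SE between libraries), against -0.31 and -0.20 before. The fitted trends thus took up only part of each difference. What was left cannot be told apart from differences between libraries for either list, because the libraries of a group spread too widely beside the change. Both lists stayed called with camera after this correction (camera adjusted p = 2.53e-12 and 9.46e-06). They were called under 29 of 29 alternatives, all of which kept the preset correlation. With an estimated correlation, the camera adjusted p was 0.754 each after the correction and 0.595 each before it. Before it, the estimated correlations between genes were 0.956 and 0.696, and the fry adjusted p was 0.366 and 0.426. An effect of palmatine on these genes, or of IL-17 if the controls lacked it, is not excluded.

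With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5 lower genes and 2 of the 10 splits gave as many on either side; the highest other was 1487. The real split gave 0 higher genes, a count that all 10 splits reach by construction, so that this comparison says nothing about chance; the highest other gave 1431. Both came from the split of control 1, palmatine 1 and palmatine 3 against the rest, with 2918 genes in all. This is the split that the first principal component makes, so the count restates that component and is no separate support for it. For gene lists, 1 of the 10 splits, the real one, gave as many as 10, and the others gave from 2 to 6. Camera with the preset correlation therefore called lists under every split.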
